A study of Mus musculus with 12 samples.

How the data were processed

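Cy3-labelled miRNA from 12 mouse epithelial samples was hybridised to custom single-colour Agilent arrays, 1 sample per array, after labelling with an LNA-based miRNA kit, per the labels' protocols. Adult epithelium was obtained by enzymatic digestion and repeated low-speed centrifugation, per the labels' protocols, and no cell sort is named there. The deposited scanner files hold spot intensity on a linear scale, and their processed signal was background-subtracted by Agilent Feature Extraction, per the file headers. The headers name version 10.5.1.1 and array design 023723, while the submitters' processing notes name version 10.1; which applied is not settled. For 1 file, reprogrammed lung replicate 3, the header blocks are missing and processed signal is rounded to 3 significant digits. The authors' value table holds log2 values of the same arrays for 2270 probes, those with 6 or 7 spots. Its method is not given in the sources used here. From the values, each column correlated best with the log2 median spot signal of its own array, taken without background subtraction (r from 0.996 to 1.000, direction as in the scanner values). Whether background was subtracted in the authors' table was not tested. Its column medians were 4.97, 4.97 and 5.00 in adult lung, 4.98, 4.97 and 4.97 in adult mammary, 4.97, 4.98 and 4.99 in reprogrammed lung and 4.98, 4.97 and 4.98 in reprogrammed mammary. How it was scaled and centred stays unknown. It was used as an alternative only. There were 0 columns of other samples.

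Each array carried 15611 spots, of which 15075 were not controls and belonged to 2579 probes. Probe names are serial numbers of the array maker. The tables used here do not pair them with miRNA names, so 0 members of the 17 miRNA lists fixed in advance could be matched, and neither list tests nor values of single miRNAs could be given. The rule fixed in advance named the 10 highest and 10 lowest changes per main comparison, and 5 and 5 in the others, among miRNAs past the threshold whose groups of arrays did not overlap. With no names it was narrowed to the 2 highest and 2 lowest probes of each comparison, and for the difference of both effects overlap was not asked for.

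Outlier spots flagged by Feature Extraction (164 to 345 per array) were left out, and 0 spots were saturated. Processed signal was scaled by each array's 75th percentile over the 631 probes well above background on all 12 arrays, since 1479 of the 2579 probes were not detected on any array. A floor common to all arrays was then set at 10.6 (3.41 on the log2 scale), the median over arrays of the 5th percentile of scaled signal among spots well above background. Log2 values were averaged over the spots of a probe. A probe counted as well above background on an array where more than a share of 0.5 of its spots were, outliers aside. The 947 probes well above background on at least 3 arrays were tested, 754 of them among the authors' values and 193 not. Where a probe was not well above background on any array of a group, a bound was given, from the brighter group's mean against the higher of the array's lowest detected signal and the probe's own.

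Tests used limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with 4 group means and no block) with Benjamini-Hochberg adjustment over 947 probes within each comparison and a threshold of 0.05. There were 8 residual degrees of freedom and 1.54 prior ones. The data were read with the data.table package (version 1.17.8), random blocks were estimated with statmod 1.5.0, and plots were drawn with matplotlib 3.10.9 and pandas 2.3.3 in Python 3.11.15. Intervals are standard errors of the limma fit unless SD is written. The axis score from adult lung to adult mammary is a projection averaged over 9 choices of 1 adult lung and 1 adult mammary array held out to set its ends.

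Slides were read from the array identifiers. Slide 1 held adult lung replicates 1 and 2, adult mammary replicate 1, reprogrammed lung replicate 3 and reprogrammed mammary replicate 4. Slide 2 held adult lung replicate 3, adult mammary replicate 4, reprogrammed lung replicate 2 and reprogrammed mammary replicate 2. Slide 3 held adult mammary replicate 2, reprogrammed lung replicate 1 and reprogrammed mammary replicate 1, and no adult lung array.

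Simulated values were drawn independently, with the fitted spread of each probe taken as the same in all groups and with no floor. The fit was tested on them over 20 runs, with 200 of the 947 probes changed. For reprogrammed lung against adult lung it recovered 66.1% of changes of 1 and 92.6% of changes of 2 on the log2 scale, with 3.57% false calls. For reprogrammed mammary against adult mammary these were 66.5%, 93.0% and 4.32%, and for the adult tissues 65.2%, 93.6% and 4.52%.

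Groups, comparisons, the test and most alternatives were fixed before the data were examined. The alternatives were the percentile over all probes, quantile normalization, no scaling, normexp background correction (offset 50), total gene signal, 3 other filters on dim probes, no floor, the authors' value table, slide as a fixed or random block, replicate number as a block, fits on only the groups compared, trend and robust options, array weights, and leaving out each of the 12 arrays. Normexp was run on median spot signal, since the mean signal column is absent from the files used. Chosen after seeing the data were the use of median signal for normexp, the restriction to probes of the authors' table and the percentile over those probes. Averaging several probes per miRNA, a species filter and list tests were not run, because probe names are not paired with miRNAs.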

Results

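MicroRNA (miRNA) levels in mouse epithelial cells were measured on 12 single-colour arrays. The arrays held 4 groups of 3 samples: adult lung, adult mammary gland, reprogrammed lung and reprogrammed mammary gland. Adult epithelial donor cells came from female mice of 10 weeks. The series title describes stroma-dependent reprogramming of adult lineages in vivo. The labels do not settle whether reprogrammed lung means cells that came from lung or cells that took on a lung fate, so each reprogrammed group was compared with both adult groups. Array brightness, taken as the 75th percentile of processed signal over the 631 probes detected on all arrays, was 2516 ± 387 in adult lung and 1427 ± 93.3 in adult mammary cells (SD, n = 3). It was 1525 ± 224 in reprogrammed lung and 842 ± 33.1 in reprogrammed mammary cells (SD, n = 3). The mean number of probes well above background was 912 in adult lung, 811 in adult mammary, 888 in reprogrammed lung and 733 in reprogrammed mammary cells. The number of arrays per group limits the precision of every value. Nothing in the labels says that replicates came from separate animals, so p-values measure only the spread between these samples, which may be technical.

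Adult lung cells stood apart from the other 3 groups. On the first principal component, which held 44.6% of the variance, the adult lung arrays lay between -24.83 and -20.80. The other 9 arrays lay between -2.47 and 16.10. Across the 631 probes detected on every array, the median correlation between adult lung and reprogrammed lung arrays was 0.921, against 0.980 among adult lung arrays. Adult mammary and reprogrammed lung arrays had a median correlation of 0.957, and adult mammary and reprogrammed mammary arrays one of 0.967. The reprogrammed lung arrays were the most spread of the 4 groups, with a median correlation of 0.954 within the group and a median probe SD of 0.34 on the log2 scale. Reprogrammed lung replicate 1 correlated best with adult mammary replicate 4 (r = 0.958), and reprogrammed lung replicate 3 with reprogrammed mammary replicate 4 (r = 0.981), an array of the same slide. These correlations are across probes, which are not independent replicates.

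**Figure D1:**
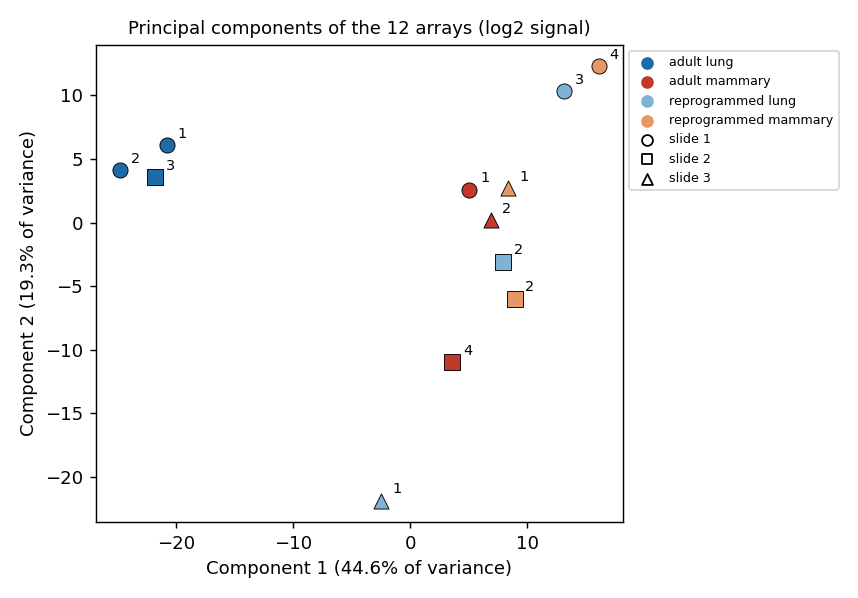
First and second principal components of normalized log2 signal over 947 probes, with axes giving each component's share of the variance; colours are groups, shapes are slides and numbers are replicates. The 3 adult lung arrays lie at the left (-24.83 to -20.80 on the first component), and reprogrammed lung replicate 1 lies lowest on the second.

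The comparison of reprogrammed lung with adult lung asks how far reprogrammed cells differed from adult cells carrying the same tissue label. Of 947 probes tested, 332 (35.1%) differed, 191 higher and 141 lower in reprogrammed lung (limma, adjusted p under 0.05). More than 2-fold changes were seen in 108 of the higher and 75 of the lower probes. UCSF034_000380 rose from 5.26 ± 0.36 in adult lung to 11.83 ± 0.81 in reprogrammed lung cells (log2 signal, SD, n = 3). Its change was 6.58 ± 0.42 (SE) on the log2 scale, or 95.4-fold, with an adjusted p of 4.3e-06, and UCSF034_000379 rose by 5.49 ± 0.31 (SE, adjusted p = 1.9e-06). UCSF034_000548 fell by 4.80 ± 0.21 (SE, adjusted p = 2.3e-07), from 8.77 ± 0.21 to 3.98 ± 0.12 (SD, n = 3). UCSF034_000547 fell by 4.05 ± 0.44 (SE, adjusted p = 0.000226). The groups did not overlap for 327 of the 332 probes that differed, and for 490 of all 947 tested, where chance gives 10% for 3 arrays against 3. With slide as a fixed block 293 probes differed. Within slides 1 and 2, UCSF034_000380 was higher by 7.13 and 6.73 and UCSF034_000379 by 5.64 and 5.80, while UCSF034_000548 changed by -4.63 and -4.89 and UCSF034_000547 by -3.22 and -3.95 (log2). Named probes were chosen among those whose groups of arrays did not overlap. The direction within slides was thus fixed by that choice, here and in the other comparisons, and only the sizes are informative. The split by direction moved both ways with the processing: it was 488 higher and 107 lower after normexp background correction and 138 and 188 with total gene signal. It was 89 higher and 223 lower with the percentile taken over all probes, and 143 and 170 after quantile normalization. It was 100 and 150 in the authors' value table, 136 and 196 with the percentile taken over that table's probes, and 53 and 305 with no scaling. The median log2 change of all tested probes was 0.14 in the main scaling, -0.05 with the percentile over all probes, -0.01 after quantile normalization, 0.03 in the authors' table and -0.39 with no scaling. All 4 named probes kept their direction under each of these scalings. Without adult lung replicate 2 the count was 204, and without adult lung replicate 3 it was 220.

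**Figure D2:**
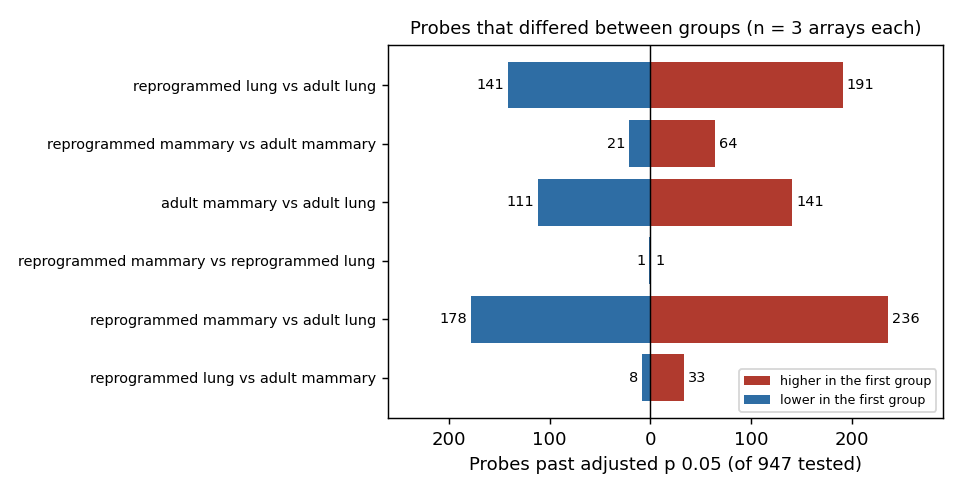
Number of probes past an adjusted p of 0.05 in each comparison of 3 arrays against 3, of 947 tested; bars to the right count probes higher in the first group named and bars to the left probes lower in it. Reprogrammed lung against adult lung had 191 and 141, and the reprogrammed groups differed at 1 and 1; with no between-array scaling and with other percentiles the split by direction changed.

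Fewer probes separated reprogrammed mammary from adult mammary cells. Of the 947 probes, 85 differed, 64 higher and 21 lower in reprogrammed mammary cells (limma), and 39 of the higher and 6 of the lower changed more than 2-fold. UCSF034_000782 rose from 7.97 ± 0.40 to 11.24 ± 1.1 (log2 signal, SD, n = 3), a change of 3.27 ± 0.73 (SE) or 9.67-fold (adjusted p = 0.0238). UCSF034_002172 rose by 3.03 ± 0.63 (SE, adjusted p = 0.0213). UCSF034_000209 fell by 1.31 ± 0.24 (SE, adjusted p = 0.0130) and UCSF034_000233 by 1.13 ± 0.23 (SE, adjusted p = 0.0206). Both of these have 1 spot per array and lie outside the authors' value table, as did 15 of the 21 lower probes and 7 of the 64 higher ones. With Feature Extraction's total gene signal the changes of UCSF034_000209 and UCSF034_000233 were -0.03 and -0.75 (limma, adjusted p = 0.896 and 0.0838), and after normexp background correction they were 0.16 and -0.15 (limma, adjusted p = 0.401 and 0.486). The groups did not overlap for all 85 probes, and for 279 of the 947 tested, where chance gives 10%. With slide as a fixed block 77 probes differed, and within each of slides 1, 2 and 3 the change of UCSF034_000782 was 4.95, 2.12 and 2.75 (log2) and that of UCSF034_002172 was 4.76, 1.82 and 2.50. On the same slides UCSF034_000209 changed by -2.04, -0.95 and -0.95 and UCSF034_000233 by -1.31, -1.13 and -0.95, where the slide 1 value of UCSF034_000209 was set against an array not well above background. The split by direction was 458 higher and 17 lower after normexp, 52 and 32 with total gene signal, 21 and 257 with no scaling, and 46 and 41 with the percentile taken over the authors' table's probes. The authors' values gave 36 probes, and limma fitted on these 6 arrays alone gave 0, with 220 at an unadjusted p under 0.05. Without adult mammary replicate 1 the count was 26, without adult mammary replicate 2 it was 30 and without reprogrammed mammary replicate 4 it was 31. UCSF034_000782, UCSF034_002172 and UCSF034_000233 each fell short of the threshold when any of those 3 arrays was left out, with adjusted p from 0.0610 to 0.0845 (limma), and all 4 named probes did so when these 6 arrays were fitted alone (0.0604 to 0.0781).

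The adult tissues were compared to find the probes that set mammary apart from lung cells. Between them 252 of 947 probes differed, 141 higher and 111 lower in adult mammary cells (limma), 108 and 60 of them by more than 2-fold. UCSF034_000901 was higher in adult mammary cells by 6.29 ± 1.30 (SE, adjusted p = 0.00664), and UCSF034_000903 by 5.38 ± 0.94 (SE, adjusted p = 0.00299). Adult lung replicate 3 differed from its group at both, with a log2 signal of 9.94 against 4.17 and 4.93 for UCSF034_000901, and was the single adult lung array of 3 to detect UCSF034_000903. Within slide 1 the difference at UCSF034_000901 was 7.75 and within slide 2 it was 2.62, and at UCSF034_000903 these were 6.18 and 2.69. Both adult lung arrays of slide 1 were at the floor for UCSF034_000903, so its 6.18 and its mean difference depend on the floor and are not exact sizes. UCSF034_000556 was lower in adult mammary cells, by -4.82 ± 0.47 (SE, adjusted p = 0.000108), and UCSF034_000547 by -4.81 ± 0.44 (SE, adjusted p = 7.2e-05). On slides 1 and 2 these were -4.96 and -5.03 for UCSF034_000556 and -5.04 and -5.03 for UCSF034_000547. For 250 of the 252 probes the groups did not overlap, as for 425 of all tested, where chance gives 10%. With slide as a fixed block 124 probes were higher and 79 lower. The split by direction became 110 higher and 155 lower with the percentile over all probes, 104 and 123 in the authors' table, 51 and 386 with no scaling, and 470 and 87 after normexp. The median change of all tested probes was 0.00 in the main scaling, -0.16 over all probes, -0.17 after quantile normalization and -0.68 with no scaling. Leaving out adult lung replicate 2, adult lung replicate 3 or adult mammary replicate 2 gave 147, 158 and 144 probes.

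Few probes passed the threshold between the tissue labels among reprogrammed cells. Of the 947 probes, 2 differed between reprogrammed mammary and reprogrammed lung cells (limma), with 181 at an unadjusted p under 0.05. The groups did not overlap for 187 of the 947 tested, where chance gives 10%. On every reprogrammed lung array but no reprogrammed mammary array, 62 probes were well above background, and 0 the other way. The reprogrammed mammary arrays were also the dimmest. The count of 2 therefore does not show that the groups were alike. UCSF034_002505 was higher in reprogrammed mammary cells by 1.14 ± 0.13 (SE, adjusted p = 0.00843), with 1.04, 1.04 and 1.33 on slides 1, 2 and 3. UCSF034_001350 was lower in reprogrammed mammary cells (log2 change -0.55 ± 0.08, SE, adjusted p = 0.0430), with floor-limited values of -0.41, -0.63 and -0.61 on the 3 slides. UCSF034_001350 was not well above background on any reprogrammed mammary array. In the main processing the bound on its higher signal in reprogrammed lung was 1.03-fold. This bound rests on the lowest detected signals and did not hold after normexp background correction. On simulated data with 200 of 947 probes changed, 66.0% of probes changed by 1 on the log2 scale and 93.0% of those changed by 2 were recovered in this comparison. With few calls the adjustment is stricter, and the simulation held no floor and no deviation shared by probes. These shares therefore do not give the power behind the count of 2. With slide as a fixed block limma called 0 probes, with 175 at an unadjusted p under 0.05, and the log2 changes stayed at 1.14 ± 0.15 for UCSF034_002505 (SE, adjusted p = 0.0790) and -0.55 ± 0.10 for UCSF034_001350 (SE, adjusted p = 0.0972). Each slide holds 1 array of each reprogrammed group, so the block left the changes as they were, while the SE rose and residual degrees of freedom fell from 8 to 6. The count was 0 without reprogrammed mammary replicate 1 (limma, 119 at an unadjusted p under 0.05), 7 without reprogrammed lung replicate 1, 15 without reprogrammed lung replicate 3 and 10 without reprogrammed mammary replicate 4. With no scaling 347 probes differed, 0 of them higher, and after normexp background correction 449 were higher and 15 lower. UCSF034_002505 stayed past the threshold in 23 of 30 other settings and fell short in 7. In those 7 its change ran from 0.28 with no scaling (limma, adjusted p = 0.309) to 1.21 with the replicate block (limma, adjusted p = 0.0575). It was 0.49 in the authors' values (limma, adjusted p = 0.0632). Its mean log2 signal in reprogrammed lung was 3.91, near the floor of 3.41, so its size depends on the scaling. UCSF034_001350 fell short in 16 of 29 settings. After normexp background correction UCSF034_001350 turned to 0.58, past the threshold in the opposite direction (limma, adjusted p = 0.00811).

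The 252 probes that separated the adult tissues had a median adult difference of 1.22 (log2). They were chosen by that difference, which raises its size and the number past 2-fold, so part of any drop from it was to be expected. The median difference in the same direction between the reprogrammed groups, which share no arrays with the adult groups, was 0.08. The median size of these probes there regardless of direction was 0.28, against 0.30 over all 947 tested. Of these 252 probes, 168 differed more than 2-fold between the adult tissues, 5 still did so in the same direction between the reprogrammed groups, and neither of the 2 probes called there was among them. The same direction was seen in 147 of the 252 (58.3%). An exact one-sided permutation of the 6 reprogrammed arrays gave p = 0.05, the smallest that its 20 splits allow, and the highest other split gave a median of 0.0775 against the real 0.0782. The splits took no account of slide, though each slide holds 1 array of each reprogrammed group. The 141 probes higher in adult mammary cells had a median log2 signal of 5.79 in adult lung, 7.77 in adult mammary, 7.31 in reprogrammed lung and 7.36 in reprogrammed mammary cells. For the 111 probes higher in adult lung the medians were 7.86, 6.28, 6.22 and 5.86 in the same order. The median difference among reprogrammed groups was 0.69 with no between-array scaling, 0.05 with the percentile over all probes and 0.10 after quantile normalization. It was 0.12 with slide as a fixed block and 0.17 with replicate number as a block. Each was taken over the probes that separated the adult tissues in that setting. With no scaling the median change of all tested probes, mammary minus lung, was -0.69 between the reprogrammed groups and -0.68 between the adult tissues. Of the probes that separated the adult tissues in that setting, 386 were lower and 51 higher in mammary cells. The 0.69 thus carries the shift of all probes and does not show a tissue difference kept in reprogrammed cells. Leaving out adult mammary replicate 1 gave 0.01, adult lung replicate 3 gave 0.03, adult mammary replicate 4 gave 0.12 and reprogrammed lung replicate 3 gave 0.13.

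**Figure D3:**
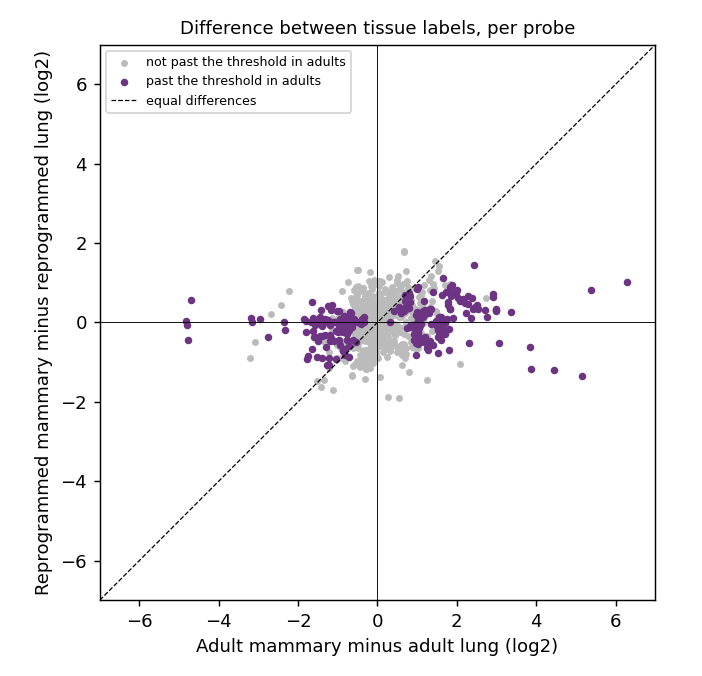
Each point is 1 of 947 probes, placed by its adult mammary minus adult lung difference (horizontal, log2) and its reprogrammed mammary minus reprogrammed lung difference (vertical, log2); purple marks the 252 probes past the threshold in adults and the dashed line equal differences. The purple points spread along the horizontal axis, by which they were chosen, with a median size of 1.22. They lie on both sides of 0 on the vertical axis, with a median size of 0.28 there and 147 of 252 in the adult direction. The median in the adult direction was 0.08. It was 0.69 with no scaling, where the median of all tested probes between the reprogrammed groups was -0.69.

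Each reprogrammed array was also placed on the line from adult lung (0) to adult mammary (1), with the line drawn from other adult arrays than those that set its ends. Reprogrammed lung scored 0.870 ± 0.158 and reprogrammed mammary 0.975 ± 0.0134 (SD, n = 3). These SDs leave out the spread from the choice of adult end arrays. Over the 9 choices the score ran from 0.842 to 1.13 for reprogrammed mammary replicate 4 and from 0.594 to 0.810 for reprogrammed lung replicate 1. The single reprogrammed lung arrays scored 0.691, 0.931 and 0.987 for replicates 1, 2 and 3.

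Because the labels leave the origin of the reprogrammed cells open, each was also set against the other adult tissue. Reprogrammed mammary against adult lung gave 414 probes, 236 higher and 178 lower (limma), and 226 higher and 166 lower with slide as a fixed block. UCSF034_000901 was higher there by 5.81 ± 1.30 and UCSF034_000380 by 5.22 ± 0.42, and UCSF034_000552 fell by 4.31 ± 0.46 and UCSF034_000548 by 4.24 ± 0.21 (log2, SE). On slides 1 and 2 these were 8.13 and 1.67 for UCSF034_000901, 5.57 and 4.91 for UCSF034_000380, -3.72 and -4.59 for UCSF034_000552, and -3.82 and -4.69 for UCSF034_000548. With array weights UCSF034_000901 fell short of the threshold (3.88, adjusted p = 0.0721). The split of this comparison by direction was 163 and 228 with the percentile over all probes, 131 and 168 in the authors' table, 14 and 531 with no scaling and 620 and 92 after normexp, and the median change of all tested probes was 0.17 in the main scaling, 0.00 over all probes and 0.02 in the authors' table. The count was 261 without adult lung replicate 2 and 272 without adult lung replicate 3.

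Reprogrammed lung against adult mammary gave 41 probes, 33 higher and 8 lower (limma). UCSF034_002175 was higher in reprogrammed lung by 2.40 ± 0.45 and UCSF034_001735 by 2.24 ± 0.43, and UCSF034_000592 fell by 2.09 ± 0.35 and UCSF034_000525 by 2.00 ± 0.39 (log2, SE). On slides 1, 2 and 3 the changes were 1.87, 3.69 and 1.64 for UCSF034_002175, 2.66, 1.83 and 2.24 for UCSF034_001735, -1.15, -2.65 and -2.45 for UCSF034_000592, and -0.98, -2.46 and -2.57 for UCSF034_000525. The reprogrammed lung array of slide 3 was at the floor for UCSF034_000592 and UCSF034_000525, so their slide 3 values and mean changes depend on the floor. With slide as a fixed block 24 probes differed. The split was 11 and 5 after normexp, 31 and 25 with total gene signal, 29 and 14 in the authors' table and 23 and 19 with the percentile over that table's probes. Without adult mammary replicate 1, adult mammary replicate 2 or reprogrammed lung replicate 2 the count was 0 (limma, with 166, 168 and 177 at an unadjusted p under 0.05). It was 11 and 21 without adult lung replicates 2 and 3, 82 without reprogrammed lung replicate 1 and 98 without reprogrammed mammary replicate 4. All 4 named probes fell short of the threshold without each of the 3 arrays that gave a count of 0, with adjusted p from 0.0548 to 0.112 (limma).

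The change from adult to reprogrammed cells of the same label differed between the tissue labels at 107 probes (limma interaction). It was more positive in mammary than in lung cells at 44 of them and more negative at 63. This contrast equals the tissue difference among reprogrammed cells minus that among adult cells. UCSF034_000380 and UCSF034_000379 rose in reprogrammed lung but changed by 0.06 and -0.17 in reprogrammed mammary cells, and the differences were -6.51 ± 0.60 (SE, adjusted p = 0.000109) and -5.66 ± 0.44 (SE, adjusted p = 4.0e-05). UCSF034_000548 fell in reprogrammed lung and changed by 0.46 in reprogrammed mammary cells, a difference of 5.26 ± 0.29 (SE, adjusted p = 3.3e-06). For UCSF034_000556 the changes were -3.93 in lung and 0.92 in mammary cells, a difference of 4.85 ± 0.67 (SE, adjusted p = 0.00192). With slide as a fixed block 102 probes differed, and without adult lung replicate 2 the count was 69. The split by direction was 66 and 49 with the percentile over all probes and 59 and 51 in the authors' table.

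**Figure D4:**
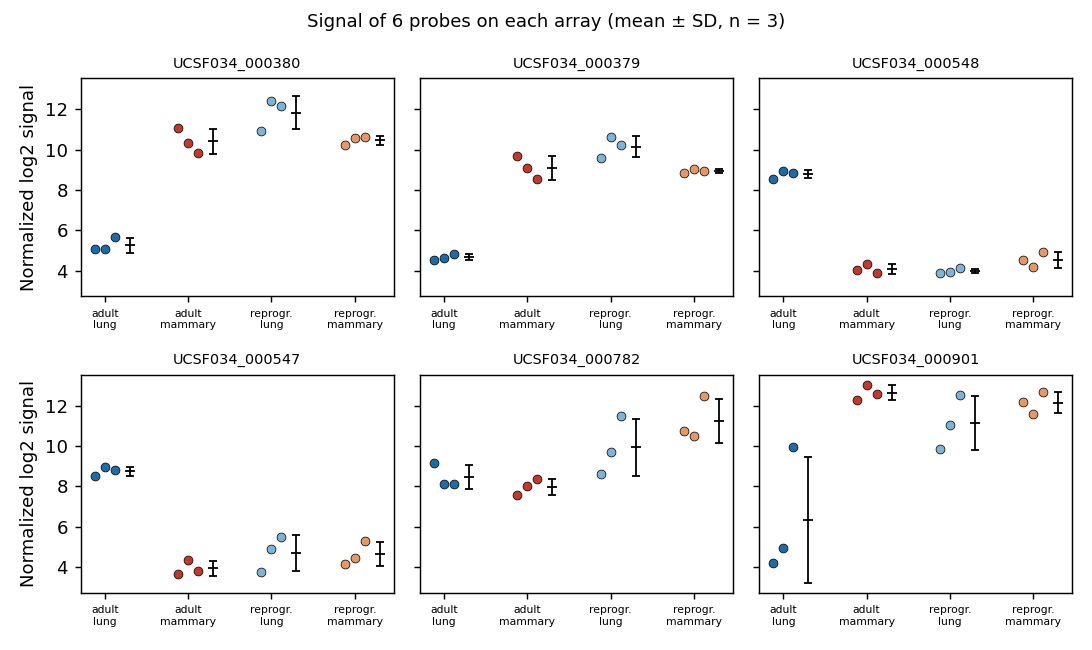
Normalized log2 signal (vertical axis) of 6 probes in the 4 groups; each point is 1 array and the bar beside it the mean ± SD of 3 arrays. UCSF034_000380 averages 5.26 in adult lung and 11.83 in reprogrammed lung, UCSF034_000548 averages 8.77 and 3.98, and adult lung replicate 3 lies at 9.94 for UCSF034_000901.

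The differences between reprogrammed and adult cells of the same label overlapped in part between lung and mammary. Of the 191 probes higher in reprogrammed lung and the 64 higher in reprogrammed mammary cells, 25 were shared, against 12.9 for independent lists (Fisher's exact test, two-sided, p = 0.000294). Of the 141 and 21 lower probes, 16 were shared, against 3.13 (Fisher's exact test, p = 2.8e-10). Of these 16, 12 lie outside the authors' value table, among 193 probes whose median change was -0.14 in lung and -0.35 in mammary cells, and 4 lie inside it, against 0.828 for independent lists there (Fisher's exact test, p = 0.00412). No probe, 0 against 9.53 for independent lists, was lower in reprogrammed lung and higher in reprogrammed mammary cells (Fisher's exact test, p = 3.4e-05), and 2 were higher in lung and lower in mammary, against 4.24 (Fisher's exact test, p = 0.281). The correlation of both changes across the 947 probes was 0.241. Probes are not independent replicates, and both comparisons share slides. Both lists also rest on the same estimate of spread for each probe, so independent lists are not an exact reference. The overlaps were tested in the main scaling only, and the split of both lists by direction changed with the scaling. In both comparisons the reprogrammed arrays were dimmer, by 0.72 in lung and 0.76 in mammary cells (log2), and the part of brightness in the overlap was not tested.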

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

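Chosen only after the result was seen were the tests of brightness, slide and other cell types for the adult lung difference, of all 3 slides for reprogrammed lung replicate 1, and of several probes per transcript at neighbouring probe numbers; the admixture test was set before, and its needed share was put on the linear scale afterwards. The change from adult to reprogrammed cells of the same label differed between lung and mammary at 107 probes by a test of the difference itself. Whether that change is an effect of reprogramming depends on what the labels name, which is not settled. Single probes with such a difference (mammary minus lung, log2) were UCSF034_000380 (-6.51), UCSF034_000379 (-5.66), UCSF034_000548 (5.26), UCSF034_000547 (4.75), UCSF034_000556 (4.85), UCSF034_002505 (0.86) and UCSF034_001350 (-0.56). UCSF034_001350 was not well above background on any adult lung or reprogrammed mammary array and on only 1 adult mammary array, and UCSF034_002505 was at the floor on 2 of 3 adult lung arrays, so both values depend on the floor and are not exact sizes. Exchanging lung and mammary labels within adult and within reprogrammed arrays, 5 of 100 drawn splits gave at least 107 probes, the real one included, and the highest other gave 191, so chance was not excluded by this count. All 5 kept the real adult groups, as 9 of the draws did, and the 91 draws that did not gave at most 0. Mixing the adult tissues within a group adds their difference to the spread of the fit. Low counts were therefore to be expected in those 91 draws, and they do not show the source of the 107 probes.

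The 3 against 3 comparisons have only 10 splits, too few for a share under 0.05. Splits that mix groups which differ also raise the spread of the fit, so low counts in them were to be expected. As many probes as in the real split were found in 1 of 10 splits for reprogrammed lung against adult lung (332, highest other 0), adult mammary against adult lung (252, highest other 0) and reprogrammed mammary against adult lung (414, highest other 0). The same held for reprogrammed mammary against adult mammary (85, highest other 2) and reprogrammed lung against adult mammary (41, highest other 20). Between the reprogrammed groups 3 of 10 splits gave at least the real 2 probes. The highest other, 28, set reprogrammed lung replicate 1 with reprogrammed mammary replicates 1 and 2, which lie on slides 2 and 3, against arrays of which 2 lie on slide 1. That points to a structure of the samples other than the groups, and it follows slides in part. The real split gave 0 probes with slide as a fixed block (limma, 175 at an unadjusted p under 0.05), but this loss says nothing of slides as the source of the 2 calls: the log2 changes were the same before and after (UCSF034_002505 1.14 ± 0.13 and 1.14 ± 0.15, UCSF034_001350 -0.55 ± 0.08 and -0.55 ± 0.10, SE), since each slide holds 1 array of each reprogrammed group, and the calls ended because the SE rose and residual degrees of freedom fell from 8 to 6.

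Adult lung differed from reprogrammed lung at 332 probes. A difference in array brightness as the whole cause was argued against: after quantile normalization, which gives every array the same distribution, 313 probes differed, among them 252 of the 332 in the same direction, 122 higher and 130 lower. The median size of change of these 252 was 1.22 before and 1.36 after, with a median SE of 0.24 and 0.29. Of the other 80, the 69 higher went from a median of 0.78 to 0.62 and the 11 lower from -0.53 to -0.63, with a median SE over the 80 of 0.22 before and 0.28 after, so the SE rose and only the higher changes shrank, and brightness as part of the cause stays open for them. Slides as the whole cause were argued against, since 293 probes differed with slide as a fixed block, 269 of them shared with the 332. Cells of other types in the adult lung preparation stay open, because 0 members of the marker lists could be matched to a probe. A change of the cells on reprogramming, which the design names, stays open and untested.

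Reprogrammed lung replicate 1 stood apart from the other arrays of its group, with a score of 0.691 on the adult axis. Mixing the adult lung profile on the linear scale into the mean of the other arrays of its group would take a share of 27.6% to give this score, but over the 10 probes more than 4-fold higher in adult lung than in adult mammary cells the median share implied by linear signal was -1.29%, and the highest 0.259%. The main axis of deviations within groups held 50.4% of their variance; slide took up 42.6% of its scores (exact permutation p = 0.241), and the array's deviation correlated at -0.24 and 0.12 with those of the other slide 3 arrays but between -0.54 and 0.56 with arrays of other slides, so slide differences cannot be told apart from sample differences. Array brightness as the cause could not be decided. Over 12 arrays the scores had r = 0.212 with brightness (exact permutation p = 0.704) and rho = 0.175 (exact permutation p = 0.686), and r = 0.247 without the 2 arrays of most extreme brightness. This met the rule set beforehand for arguing against brightness, but so few arrays leave a stronger relation possible. Replicates 1 and 3 of reprogrammed lung had brightness deviations of 0.15 and 0.10 (log2) and scores of 19.6 and -16.8. The design names no biological difference between replicates, so none was tested.

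Neighbouring probe numbers had similar profiles, with a median r of 0.864 over 353 pairs against -0.03 in random order. Whether several probes report the same miRNA or close relatives stays open, because in 0 adjacent pairs do both probes carry a name other than their number. Neighbouring spots are argued against, since 262 pairs with no spots within 10 grid steps of each other had a median r of 0.890. Counting adjacent probes with r above 0.9 once lowers 332 to 243, 252 to 168, 85 to 80 and 107 to 76. This can also join different miRNAs with like profiles. It leaves apart probes with like profiles and distant numbers. Between the mammary groups, UCSF034_000782 changed by 4.95, 2.12 and 2.75 and UCSF034_002172 by 4.76, 1.82 and 2.50 on slides 1, 2 and 3 (log2). Named probes may therefore repeat the same signal, and the number of miRNAs behind the counts of probes is not known.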

How the results depend on the processing

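The percentile over probes of the authors' table, the restriction to its probes and normexp on the median signal were chosen after seeing the data. Of 766 alternative values of the named probes, 695 kept their direction and stayed past the threshold, 69 kept only their direction and 2 turned, both after normexp: UCSF034_000209 in the mammary comparison (0.16) and UCSF034_001350 between the reprogrammed groups (0.58). The turned value of UCSF034_001350 was past the threshold. Where the cause of a moved count is not given, the cause was not tested.

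Reprogrammed lung against adult lung gave 595 probes with normexp and 185 with no filter on dim probes. Reprogrammed mammary against adult mammary gave 278 with no scaling, 475 with normexp, 50 for probes detected on all 12 arrays, 35 with no filter, 36 in the authors' table, 0 with only these groups fitted (limma, 220 at an unadjusted p under 0.05) and 130 with array weights. Adult mammary against adult lung gave 437 with no scaling, 557 with normexp, 132 with no filter and 452 with array weights. Reprogrammed mammary against adult lung gave 712 with normexp and 263 with no filter. Reprogrammed lung against adult mammary gave 69 with no scaling, 16 with normexp, 18 for probes detected on all arrays, 2 with no filter, 85 with no floor, 24 with slide as a fixed block, 25 with only these groups fitted, 68 with trend and robust options, 96 with array weights and 69 with only the probes of the authors' table. The difference of both effects gave 67 for probes detected on all arrays, 58 with no filter and 253 with array weights. The normexp offset is added before scaling, which raises low signals more on the dimmer arrays. Its part in the moved counts was not tested, since the signal column and background method changed with it. The estimate of array weights stopped before reaching its tolerance.

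Between the reprogrammed groups limma's count was 0 with the percentile over all probes (173 at an unadjusted p under 0.05), 5 after quantile normalization, 347 with no scaling, 464 with normexp, 15 with total gene signal, 1 for probes detected on all arrays, 26 for those detected on at least 1, 11 with no filter, 5 with no floor, 0 with slide as a fixed block (175 unadjusted), 0 with only these groups fitted (132 unadjusted), 20 with trend and robust options, 37 with array weights, 4 with only the probes of the authors' table and 6 with the percentile over them.

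Leaving out each array in turn gave 204 to 378 probes for reprogrammed against adult lung, 26 to 95 for reprogrammed against adult mammary, 144 to 285 for the adult tissues, 0 (119 unadjusted) to 15 for the reprogrammed groups, 261 to 450 for reprogrammed mammary against adult lung, 0 (166 to 177 unadjusted) to 98 for reprogrammed lung against adult mammary and 69 to 149 for the difference of both effects. The correlation of both effects, 0.241, was 0.163 to 0.299 without single arrays, 0.297 with normexp, 0.191 in the authors' table, 0.290 with slide as a fixed block and 0.194 with only its probes.

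Replicate numbers are shared between groups, and whether they pair the samples is not settled. The deviations of same-numbered arrays from the other arrays of their groups had correlations of -0.05, 0.26 and -0.04 in lung and 0.18, -0.29 and -0.23 in mammary cells. Not every array's deviation correlated best with that of its own number. These values gave no sign of pairing, but with so few arrays per group they cannot exclude it. With the replicate block the counts were 296 for reprogrammed against adult lung, 56 for reprogrammed against adult mammary, 174 for the adult tissues, 1 for the reprogrammed groups, 289 for reprogrammed mammary against adult lung, 42 for reprogrammed lung against adult mammary and 76 for the difference of both effects, and the median difference of 0.08 between the reprogrammed groups at probes that separated the adult tissues was 0.17. The reprogrammed mammary arrays were the dimmest, so signal over background limits what could be detected there. Averaging probes per miRNA, a species filter and list tests were not run.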

Other observations

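This comparison of probes inside and outside the authors' value table was chosen after the values were seen, and no test of the difference was made. The 193 tested probes outside had a median change of -0.35 (log2) in reprogrammed against adult mammary cells, and the 754 inside a median of 0.05. In reprogrammed against adult lung cells these medians were -0.14 and 0.20. Between the reprogrammed groups they were -0.22 and 0.01. What these probes measure is not given in the sources used here.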
